A study of Mus musculus with 6 samples.

How the data were processed

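Matrices of filtered UMI counts per gene and barcode were used as deposited; Cell Ranger 3.0.2 for the E9.5 libraries and 3.1.0 for the later ones made them per the file headers, on mm10 per the submitters' processing notes, which also name Seurat. Per the labels, the mice were wild-type Cdh5-cre;R26mTmG embryos, the embryos of a stage were pooled, and cells were enriched with CD31-FITC and magnetic sorting. The series text also mentions an inducible Cre line, and which embryos carried it is not given in the sources used here. The E9.5 matrices list 27998 genes and the later ones 31053, of which 27514 share an identifier and were analysed; the others held between 0.0920% and 0.238% of the UMIs of a library and were not analysed. Gene table, Cell Ranger version and dissection therefore changed together between E9.5 and E12.5. Barcodes of E12.5 replicate 1 came from another 10x barcode set than those of the other libraries. Whether the 2 libraries of a stage were independent is not stated, so p-values measure the spread between these libraries.

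Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, and of these the cells with the highest Scrublet doublet scores in each library, 0.8% per 1000 cells, were removed. The doublet share was set after an automatic threshold had failed in E15.5 replicate 1. Of 43049 barcodes 36721 were kept. Median mitochondrial shares were 3.67, 3.36, 3.48, 6.42, 5.00 and 4.15% in library order. Cells of all libraries were clustered together with scanpy and without batch correction (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1.0), giving 46 clusters named from marker lists of 14 classes. Cells of endothelial clusters were clustered again in the same way, giving 22 clusters named from 10 lists. Genes of the 12 lists compared between classes, and mitochondrial, ribosomal, Xist and Y-linked genes, were left out of both clusterings. The exact naming rule, including the rule that an endothelial cluster with at least 50% of the markers of another class is mixed, was settled after the clusters had been seen. Mixed clusters were left out, which gave 7631 endothelial-like cells. A class at 0 cells is given with the share that 3 cells would make.

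UMIs of endothelial-like cells were summed per library, giving 10151215, 13338271, 11041099, 22472380, 13788933 and 26012894 UMIs in library order, with medians of 7807, 19542, 6728, 10503, 7090 and 12007 per cell. The sums were normalized with TMM, filtered with filterByExpr and fitted with edgeR quasi-likelihood F-tests over all 3 stages together, with 3 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg at 0.05. The common biological coefficient of variation was 20.1%. Replicates differed less at E9.5 (chi-square per degree 9.95) than at E12.5 and E15.5 (68.2 and 49.6). A first fit used a robust estimate of the spread, outside the plan. Its counts had been seen when a self-test on simulated counts showed false calls. Defaults were then used for all results before their counts were seen. Classes with at least 30 cells in each library compared were fitted in the same way, and brain-like cells against all others with a class-by-stage term and a library term. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one. In 200 genes altered 2-fold or 4-fold, stage fits recovered 42 to 53% and 97 to 99%. False calls were 15 of 155, 17 of 167 and 18 of 160. Random lists (0 of 20 called) do not test lists of correlated genes. The arterial fit of E15.5 against E12.5 recovered 18 and 84% with 12 of 114 false, and the class-by-stage fit 61 and 94% with 20 of 175 false.

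Named genes were chosen by a rule set in advance. It takes genes that passed, did not overlap between the groups' libraries and reached 20 CPM, and names the 12 largest rises and falls (8 within a class or for the class-by-stage term), leaving out globins, markers of other cell types, Xist, Y-linked genes and unnamed, ribosomal or mitochondrial gene models. Up to 4 genes per list and those that passed against its direction are added, with Cdh5 and Pecam1. All 7 genes that passed from E12.5 to E15.5 are named, mt-Atp8 among them outside the rule. Some genes that met the rule are not reported here. A gene at 0 UMIs in a stage is given as a lower bound on the fold with a floor of 3 UMIs over the libraries of that stage, and a gene at 1 to 3 UMIs as a ratio with a 95% exact binomial interval of the counts. Positions are from GENCODE M21 on GRCm38. Of 3539 genes in the later table alone, some share exons with genes in both tables. The 102 tested genes with such an overlap had medians of -0.37 and -0.34 from E9.5 to E12.5 and E15.5, against 0.05 and 0.04 for the other 12687. Alternatives were RLE normalization, DESeq2, no filter, replicate number as a block, each library left out, only the compared stages in the fit, doublets kept, stricter cell filters (2000 UMIs, 1000 genes, 5% mitochondrial), equal and thinned cells (2000 UMIs), equal numbers of arterial cells per library (the only class with enough in each), other resolutions, an endothelial gate on each cell's own counts, and added after the data were seen, the robust spread, mixed clusters kept, and genes far higher in other cells or with overlapping exons left out. The gate left 2 and 0 cells in the E9.5 libraries, so it was used for E15.5 against E12.5 alone. Versions were Python 3.11.15, scanpy 1.11.5, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.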

Results

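The data were single-cell RNA counts of endothelial cells collected from mouse embryos at embryonic days E9.5, E12.5 and E15.5, with 2 libraries per stage. Dissociated tissue had been enriched with magnetic beads for cells bearing CD31, the product of Pecam1, and sequenced with the 10x Genomics 3-prime assay, which counts each captured mRNA by a unique molecular identifier (UMI). The mice carried a Cdh5-driven Cre and a membrane-reporter allele that turns from red to green after Cre acts. Whole embryos were used at E9.5 and embryos without tail, limbs and liver later, so a change of dissection coincided with the first interval. The 6 libraries, in order of stage and replicate number, held 64338721, 104577386, 38784772, 93367151, 53458243 and 114622229 UMIs over 7296, 5169, 6596, 9959, 5361 and 8668 barcodes. After filtering, 6608, 4343, 5714, 8409, 4596 and 7051 cells were kept, with medians of 8054, 20533, 4881, 7269, 8518 and 11028 UMIs per cell.

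Cells were grouped by clustering and named from marker genes listed before the data were examined. Endothelial-like cells, with Pecam1, Cdh5 and related transcripts, made up 15.2 ± 2.08% of kept cells at E9.5, 21.2 ± 1.03% at E12.5 and 26.5 ± 7.27% at E15.5 (mean ± SD, n = 2 libraries per stage). Nucleated erythroid cells with embryonic globins were the largest other named class at E9.5, at 22.2 ± 5.71%, against 2.49 ± 1.32% and 0.778 ± 0.961% later. Epithelial cells took 12.8 ± 0.296%, 1.76 ± 0.405% and 0.394 ± 0.336% in the same order, and neural crest or glial cells 6.28 ± 1.46%, 0.661 ± 0.242% and 0.268 ± 0.298%. Macrophages with C1q genes were at 0 of 6608 and 0 of 4343 cells at E9.5, which allows shares of up to 0.0454% and 0.0691%, and made up 24.6 ± 2.87% at E12.5 and 7.14 ± 4.92% at E15.5. This does not show a loss, since 2 unnamed clusters with 10 and 8 of the 10 macrophage markers held 733 and 109 of 4596 and 1300 and 479 of 7051 cells at E15.5, against 161 and 188 of 5714 and 23 and 446 of 8409 at E12.5. Other leukocytes or blood progenitors reached 6.93 ± 5.33% and 24.5 ± 21.1% at the later stages, against 0.0303 ± 0.0428% at E9.5. Mesenchymal cells made up 20.3 ± 6.02% at E12.5, and neural cells 6.96 ± 1.98% at E12.5.

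Smaller classes included cardiomyocytes and hepatocytes at E9.5 (3.21 ± 0.474% and 2.25 ± 0.362%). Chondrocytes, mural cells and skeletal muscle made up 3.03 ± 0.738%, 2.27 ± 0.297% and 1.30 ± 0.420% at E12.5. Clusters that carried markers of more than 1 class took 0 (bounds as for macrophages), 0.974 ± 1.13% and 11.7 ± 7.90%, and clusters without a name 38.0 ± 8.27%, 6.74 ± 1.18% and 22.1 ± 5.29%. No share passed an exact permutation test of a monotone trend with embryonic day, which with 6 libraries can give no p below 0.0222. Erythroid, epithelial and neural crest or glial shares reached that smallest value (rho = -0.956, exact p = 0.0222, adjusted p = 0.0978), while the endothelial share gave rho = 0.837 (exact p = 0.0667, adjusted p = 0.21). The enrichment itself sets the share of non-endothelial cells, so these shares describe the libraries rather than the embryos.

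Within the 1100, 595, 1253, 1721, 1455 and 1507 endothelial-like cells of the 6 libraries, 8 classes could be named. Arterial cells with Gja4, Hey1 and Dll4 made up 18.9 ± 7.54%, 16.1 ± 1.39% and 6.91 ± 0.831% at E9.5, E12.5 and E15.5. They were the only class with at least 30 cells in each library. Endocardial cells with Npr3, Nfatc1 and Gata4 made up 18.9% and 12.1% of the E9.5 libraries, 6.35 ± 1.87% at E12.5 and 2.31 ± 1.30% at E15.5 (rho = -0.956, exact p = 0.0222, adjusted p = 0.0978). Brain-like endothelial cells with Mfsd2a, Slco1c1 and Foxq1 were at 0 of 1100 and 0 of 595 cells at E9.5, which allows shares of up to 0.273% and 0.504%, and made up 16.8 ± 8.45% at E12.5 and 13.1 ± 8.44% at E15.5. Lymphatic cells with Prox1, Pdpn and Reln followed the same course, at 0 with the same bounds and then 7.65 ± 1.04% and 5.66 ± 1.62%. A capillary class with Gpihbp1, Fabp4 and Cd36 went from 0, again with these bounds, through 0.468 ± 0.324% to 49.5 ± 1.95%, in 1 cluster mostly of E15.5 replicate 1 (91.9%, 5 of 8 markers) and 1 of replicate 2 (99.1%, 8 of 8) (rho = 0.970, exact p = 0.0222, adjusted p = 0.0978). Venous cells made up 38.4 ± 8.68%, 2.18 ± 1.27% and 4.10 ± 1.24%, sinusoidal cells with Stab2 and Oit3 4.81 ± 3.48%, 0.697 ± 0.0827% and 2.18 ± 1.68%, and 11 cells named hemogenic, with Runx1 but led by leukocyte genes such as Fcer1g and Spi1, 0.616 ± 0.158% at E9.5 and 0 later (up to 0.239%). Unnamed clusters held 21.8 ± 9.60%, 49.8 ± 9.57% and 16.2 ± 12.9%. The genes that define the capillary and venous classes themselves changed with stage, so their shares are not counts of a fixed cell type.

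**Figure D1:**
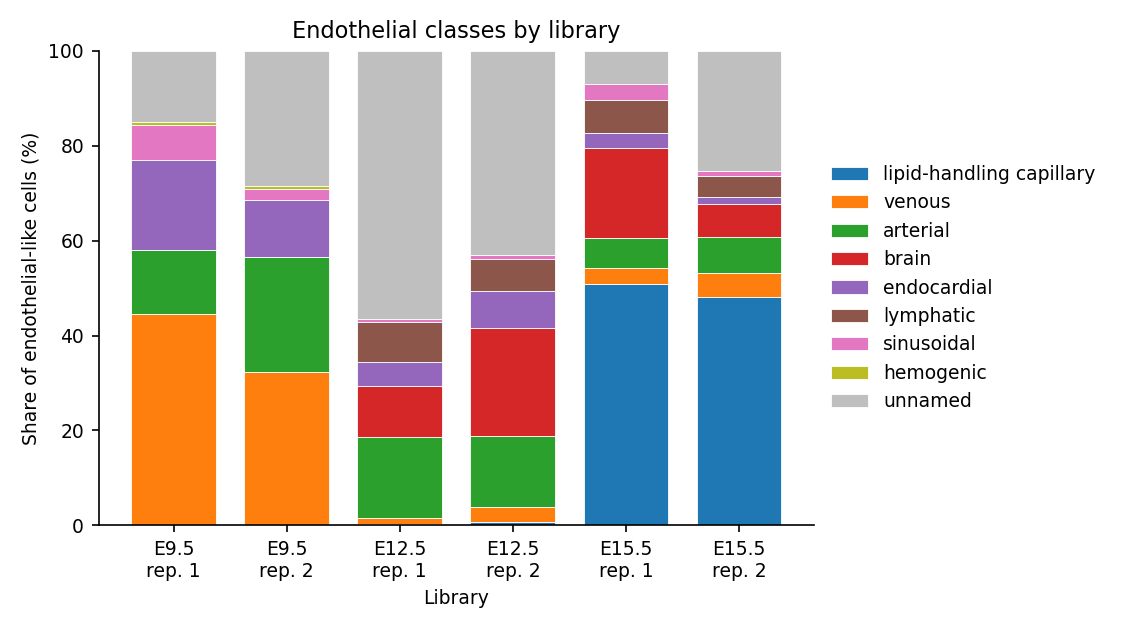
Share of endothelial-like cells (percent, vertical axis) in each named class, for each of the 6 libraries (horizontal axis). Brain-like and lymphatic cells appear only in the 4 later libraries, and the capillary class takes 50.9% and 48.2% of the 2 E15.5 libraries.

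The comparison of E12.5 with E9.5 asked which genes changed in endothelium between early vessel formation and the stage at which organs acquire their own vascular beds. UMIs were summed over all endothelial-like cells of a library, log2 changes are given ± SE, and CPM (library-scaled UMI counts) are means ± SD of 2 libraries. Etv2, which encodes a transcription factor needed for the first endothelial and blood progenitors (chromosome 7, 30633616 to 30635852), fell by 7.66 ± 0.30 (adjusted p = 2.13e-05), from 107 ± 9.58 to 0.465 ± 0.266 CPM. The RNA-binding regulator Lin28a (chromosome 4, 134003330 to 134018841) fell by 8.48 ± 0.44 (adjusted p = 7.08e-05), and the zinc-finger gene Sall4 fell by 5.99 ± 0.38. Cyp26a1, whose product degrades retinoic acid, fell by 7.43 ± 0.60, from 46.2 ± 19.6 to 0.312 ± 0.211 CPM, and the imprinted gene Phlda2 fell by 6.23 ± 0.42. Fbln5 (chromosome 12, 101746565 to 101819055) was at 0 UMIs at E9.5 and 34.9 ± 9.20 CPM at E12.5, at least 277-fold higher, and Eln (chromosome 5, 134702593 to 134747323) was 637-fold (interval 176 to 5263) higher. The matrix gene Mgp rose by 6.62 ± 0.83, and the fatty-acid-binding gene Fabp4 (chromosome 3, 10204088 to 10208576) by 8.33 ± 1.41. Palmd rose by 7.22 ± 0.41, Kctd17 by 6.64 ± 0.25 and Rgcc by 6.45 ± 0.45. Apod, Fbxl7 and Spock2, at 1 to 3 UMIs at E9.5, were 668-fold (interval 119.5 to 26390), 633-fold (interval 216 to 3073) and 411-fold (interval 114 to 3399) higher.

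Pecam1, which encodes the antigen used for enrichment (chromosome 11, 106654217 to 106750628), rose by 1.73 ± 0.20 (adjusted p = 7.89e-04), from 118 ± 3.02 to 392 ± 35.3 CPM. Cdh5, whose promoter drives the Cre (chromosome 8, 104101625 to 104144511), rose by 1.18 ± 0.18 (adjusted p = 0.00266), from 363 ± 3.05 to 822 ± 93.7 CPM. The lymphatic chemokine gene Ccl21a (chromosome 4, 42772860 to 42773993) was at 0 UMIs at E9.5 and at least 1619-fold higher at E12.5, but it has near-identical paralogs, so its locus is uncertain. Of the 12 largest falls, 7 cannot be read as expression changes alone. Fdx1l, Hgs, Ece2, Raver1, Ctla2b and Pelo share exonic bases with a gene that only the later libraries' gene table lists, and Srp54c has close paralogs. Their values were at least 1454-fold, 880.4-fold (interval 157 to 34830) and 664-fold (interval 227 to 3222) lower for the first 3, and falls by 6.33 ± 0.44, 5.76 ± 0.25 and 7.64 ± 0.28 for Ctla2b, Pelo and Srp54c. In all, 4271 of 12789 genes tested passed, 2426 higher and 1845 lower at E12.5. Left-out libraries mattered here, as the count was 1829 without E9.5 replicate 1 and 1268 without E9.5 replicate 2. Without E9.5 replicate 2, Cdh5 gave adjusted p = 0.0541 and Fabp4 adjusted p = 0.0526.

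**Figure D2:**
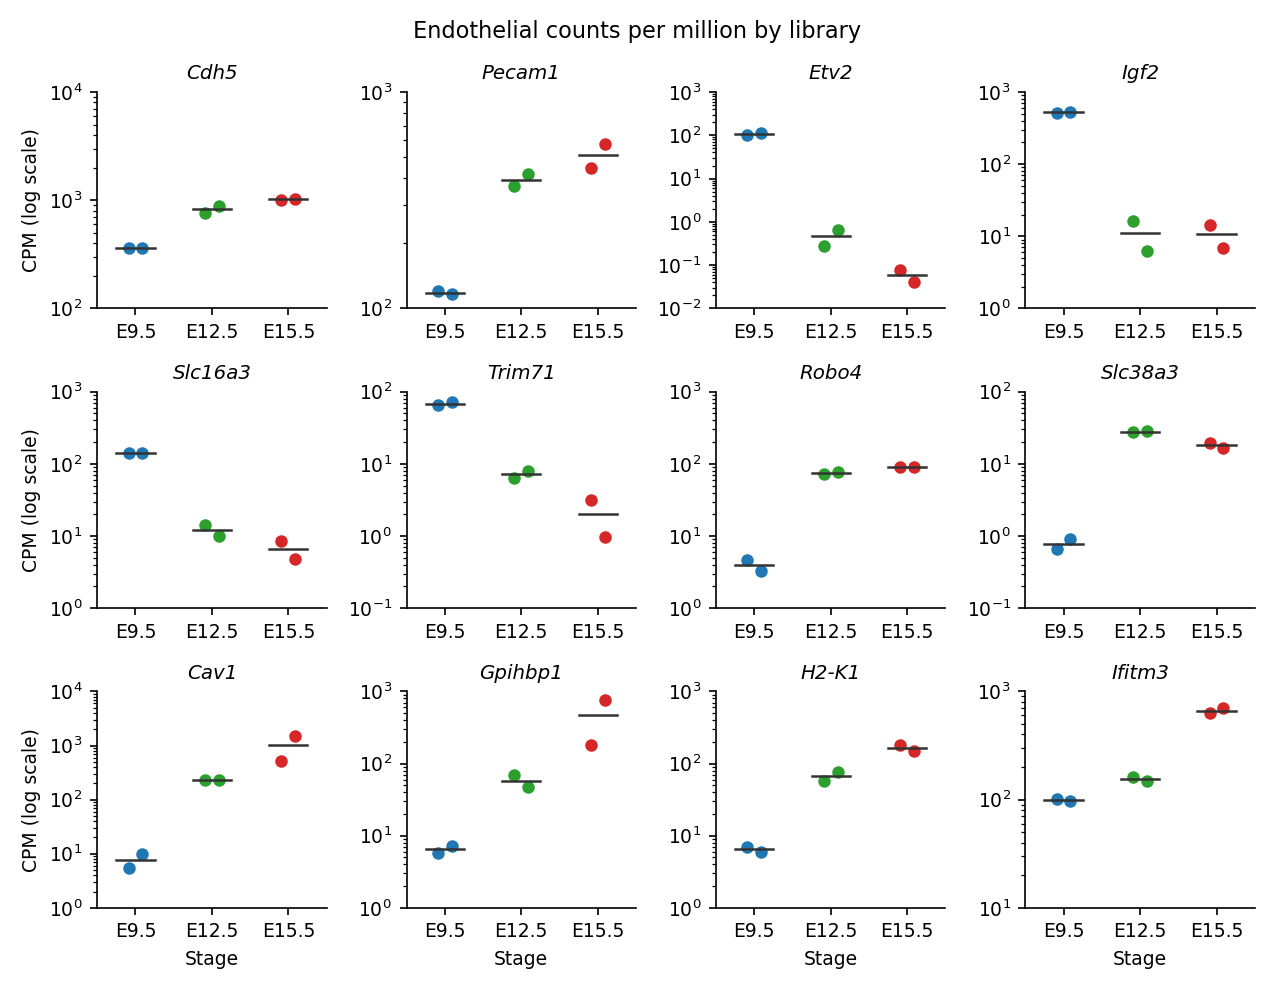
CPM (log scale, vertical axis) of 12 genes in the summed endothelial-like cells of each library (points) and the mean of each stage (lines, n = 2). Etv2, Igf2, Slc16a3 and Trim71 are highest in both E9.5 libraries, and Robo4, Slc38a3, Cav1, Gpihbp1 and H2-K1 are lowest there.

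Gene lists chosen in advance were tested next with camera, and medians are of log2 changes. An adjusted p given as estimated used a correlation between genes estimated from the data in place of the preset one. The amino-acid transporter gene Slc38a3 rose by 5.12 ± 0.26 (adjusted p = 3.88e-05), the lysolipid transporter gene Mfsd2a (chromosome 4, 122946850 to 122961188) by 7.19 ± 0.55, from 0.226 ± 0.213 to 31.7 ± 12.7 CPM, and the efflux-pump gene Abcb1a by 4.90 ± 0.38. Slc16a1 and Bsg of the same list fell by 1.76 ± 0.19 and 0.81 ± 0.20, and Bsg did not pass without E9.5 replicate 1 or 2 (adjusted p = 0.0561 and 0.152). In the blood-brain barrier list 17 of 26 rose and 2 fell, 19 and 2 adjusted over the list alone (median 1.35, adjusted p = 2.44e-09, or 0.243 estimated). The Wnt-response genes Foxq1 and Nkd1 rose by 4.15 ± 0.48 and 1.55 ± 0.24. In the Wnt response list 7 of 15 rose and 0 fell, also adjusted over the list alone (median 0.95, adjusted p = 0.00816, or 0.422 estimated). Without E12.5 replicate 2 that list gave adjusted p = 0.0567. Robo4, which encodes an endothelial guidance receptor, rose by 4.25 ± 0.21 (adjusted p = 3.88e-05), from 3.94 ± 0.965 to 74.6 ± 2.87 CPM, and Trp53i11, Pgf and Apln by 2.55 ± 0.17, 3.18 ± 0.35 and 2.04 ± 0.25. In the VEGF and tip-cell list 12 of 20 rose and 0 fell, 14 and 1 adjusted over the list alone (median 1.04, adjusted p = 1.50e-06, or 0.243 estimated). Among shear-stress genes, Procr, Cav1 and Klf4 rose by 2.53 ± 0.22, 4.89 ± 0.53 and 2.63 ± 0.34. In the shear stress list 8 of 11 rose and 0 fell, 9 and 0 adjusted over the list alone (median 1.74, adjusted p = 3.75e-05, or 0.243 estimated).

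Some genes of the vessel wall and of arterial and lymphatic identity also rose. The basement-membrane genes Col15a1 and Col4a2 rose by 4.25 ± 0.37 and 1.98 ± 0.21, while Fn1 fell by 1.34 ± 0.27. In the basement membrane and matrix list 16 of 22 rose and 2 fell, also adjusted over the list alone (median 1.21, adjusted p = 2.04e-08, or 0.243 estimated). Fn1 and Emilin1, the other fall, gave adjusted p = 0.0652 and 0.0650 without E9.5 replicate 2, and Emilin1 0.0828 without E9.5 replicate 1. The chemokine-receptor gene Cxcr4 and the Notch ligand genes Jag2 and Jag1 rose by 2.86 ± 0.30, 2.69 ± 0.33 and 1.94 ± 0.29, and the Notch target Hey1 fell by 0.80 ± 0.21. In the arterial and Notch list 10 of 22 rose and 1 fell, 11 and 1 adjusted over the list alone (median 0.69, adjusted p = 3.35e-04, or 0.243 estimated). Hey1 lost its call without E9.5 replicate 1 or 2 or E12.5 replicate 2 (adjusted p = 0.0537, 0.196 and 0.0832). Prox1, the lymphatic master regulator, rose by 2.77 ± 0.36 (adjusted p = 0.00138), and Ptx3 was 222-fold (interval 61.1 to 1834) higher. Foxc2 fell by 2.20 ± 0.25 and Lyve1 by 1.31 ± 0.36. In the lymphatic list 7 of 12 rose and 2 fell, also adjusted over the list alone (median 1.42, adjusted p = 0.00915, or 0.455 estimated). Lyve1 gave adjusted p = 0.178, 0.104 and 0.0934 without E9.5 replicate 1, E12.5 replicate 1 or 2.

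The MHC class I gene H2-K1, whose product presents peptides to T cells, rose by 3.37 ± 0.23 (adjusted p = 9.07e-05). The peptide-loading gene Tapbp rose by 1.88 ± 0.24, whereas the interferon genes Ifitm1 and Ifitm2 fell by 3.65 ± 0.44 and 1.21 ± 0.18. In the MHC class I and interferon list 17 of 24 rose and 2 fell, 18 and 2 adjusted over the list alone (median 2.76, adjusted p = 3.75e-05, or 0.243 estimated). Macrophage transcripts rose in the same sums, since C1qb was 376-fold (interval 67.3 to 14900) higher, at 15.1 ± 2.68 CPM, and Cx3cr1 rose by 4.25 ± 0.47. Of 10 macrophage markers 9 rose (median 8.12, adjusted p = 9.42e-10, or 0.243 estimated, and median 4.84 with genes at 0 UMIs set to their bound).

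Other lists were lower at E12.5. Slc16a3, which encodes the lactate exporter of glycolytic cells, fell by 3.56 ± 0.29 (adjusted p = 1.89e-04), from 141 ± 2.65 to 12.1 ± 2.76 CPM. The hypoxia target Bnip3 fell by 3.25 ± 0.27 and Pfkl by 2.00 ± 0.19, while Pgk1 rose by 1.53 ± 0.19. In the glycolysis and hypoxia list 3 of 22 rose and 14 fell, also adjusted over the list alone (median -1.57, adjusted p = 4.18e-09, or 0.243 estimated). Of the other rises, Pfkp and Hk1, the calls were lost without any of the E9.5 and E12.5 libraries (adjusted p = 0.254 and 0.240 without E9.5 replicate 1). In the early-embryo list, Trim71 and Arid3b fell by 3.24 ± 0.38 and 2.21 ± 0.34 beside Lin28a and Sall4. In the early-embryo and oncofetal list 0 of 13 rose and 9 fell, 0 and 10 adjusted over the list alone (median -1.78, adjusted p = 2.44e-09, or 0.243 estimated). Of replication genes, Cdc6 fell by 1.61 ± 0.21 (adjusted p = 0.00129) and Mcm7 by 1.00 ± 0.18. In the S phase list 0 of 30 rose and 14 fell, 0 and 21 adjusted over the list alone (median -0.63, adjusted p = 1.14e-05, or 0.452 estimated). The mitotic kinase gene Bub1 fell by 1.11 ± 0.17. In the G2 and M phase list 0 of 30 rose and 16 fell, 0 and 17 adjusted over the list alone (median -0.66, adjusted p = 8.89e-05, or 0.455 estimated). Igf2, an imprinted growth factor gene, fell by 5.59 ± 0.53 (adjusted p = 3.68e-04), from 522 ± 17.7 to 11.1 ± 6.96 CPM, and Dlk1 by 3.02 ± 0.33. Gnas rose by 1.89 ± 0.20. In the imprinted growth genes list 3 of 18 rose and 6 fell, also adjusted over the list alone (median -0.20, adjusted p = 0.0127, or 0.243 estimated). That list gave adjusted p = 0.0567 without E12.5 replicate 2. The other 2 rises, Plagl1 and Sgce, did not pass without E9.5 replicate 1 (adjusted p = 0.0929 and 0.0661) or 2.

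Hoxb5 fell by 1.97 ± 0.23 (adjusted p = 8.35e-04), Hoxb2 by 3.16 ± 0.39 and Hoxd1 by 4.87 ± 0.65. In the Hox groups 1 to 5 list 0 of 12 rose and 8 fell, also adjusted over the list alone (median -1.67, adjusted p = 1.57e-04, or 0.243 estimated). Among groups 6 to 13, Hoxc9 fell by 3.74 ± 0.46, whereas Hoxd8 rose by 1.25 ± 0.41. In the Hox groups 6 to 13 list 1 of 14 rose and 6 fell, 2 and 6 adjusted over the list alone (median -0.66, adjusted p = 0.0614). Hoxd8 gave adjusted p = 0.158, 0.0683 and 0.1998 without E9.5 replicate 1, E12.5 replicate 1 or 2. The endocardial growth-factor gene Nrg1 fell by 2.81 ± 0.23, and Snai2, which drives the transition to mesenchyme in heart cushions, rose by 2.65 ± 0.37. In the endocardial list 3 of 16 rose and 8 fell, also adjusted over the list alone (median -1.36, adjusted p = 0.00492, or 0.455 estimated). The endocardial list gave adjusted p = 0.0511 without E12.5 replicate 1. Its other 2 rises, Postn and Cdh11, were lost without E9.5 replicate 1 (adjusted p = 0.0669 and 0.154) or 2.

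Lists that did not pass as sets still held genes that did. Among venous genes Aplnr, Nr2f2 and Nrp2 rose by 1.31 ± 0.17, 1.29 ± 0.19 and 1.48 ± 0.22. The TGF-beta pathway genes Ltbp4 and Tgfbr2 rose by 2.53 ± 0.23 and 1.78 ± 0.17 and Tmem100 fell by 1.46 ± 0.27. Tcf15 and Meox2, transcription factor genes of lipid-transporting capillaries, rose by 2.45 ± 0.23 and 4.49 ± 0.66. For venous genes 4 of 10 rose and 1 fell (median 0.65, adjusted p = 0.147), for BMP and TGF-beta genes 8 of 17 and 3 (median 0.50, adjusted p = 0.231) and for lipid handling 4 of 15 and 1 (median 0.90, adjusted p = 0.0546). Counts adjusted over the list alone were 5 and 2, 8 and 3, 4 and 1, with estimated adjusted p = 0.545, 0.534 and 0.534 in that order. Jam2 and Icam1, adhesion genes, rose by 6.46 ± 0.51 and 2.36 ± 0.34, and Zfp36, an early response gene, by 2.35 ± 0.33. In the same way, for leukocyte adhesion 7 of 15 rose and 3 fell (median 0.56, adjusted p = 0.0614), for oxidative phosphorylation 5 of 26 and 1 (median 0.28, adjusted p = 0.264) and for dissociation stress 9 of 20 and 1 (median 0.68, adjusted p = 0.0614). They were, adjusted over the list alone, 7 and 3, 3 and 0, 9 and 1, with estimated adjusted p = 0.534, 0.803 and 0.534 in that order. Some members called against their list's direction lost that call without E9.5 replicate 2, namely Apoe of the lipid list (adjusted p = 0.0583), Tgfb1 and Bmper (0.0707 and 0.0680), F11r, Jam3 and Ackr1 (0.0704, 0.160 and 0.119), Cox5a (0.197) and Hsp90aa1 (0.0518), all but Apoe also without another library.

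Markers of other cell types in the same endothelial sums moved with stage as well. The epithelial keratin gene Krt8 fell by 5.95 ± 0.32, the mesenchymal gene Twist1 by 4.70 ± 0.23, and Trf, a hepatocyte marker that brain endothelium also expresses, rose by 4.56 ± 0.29. Embryonic globin Hba-x was at 679 ± 102 CPM at E9.5 and 20.9 ± 20.7 at E12.5. For erythroid 0 of 11 rose and 4 fell (median -1.23, adjusted p = 0.0262), for megakaryocyte 4 of 5 and 1 (median 3.82, adjusted p = 0.0252) and for other leukocyte 5 of 10 and 1 (median 5.76, adjusted p = 0.0458). Adjusted over the list alone, they were 1 and 5, 4 and 1, 5 and 1, with estimated adjusted p = 0.364, 0.243 and 0.534 in that order. Likewise for neural 5 of 6 rose and 0 fell (median 2.33, adjusted p = 0.0142), for epithelial 0 of 5 and 3 (median -3.36, adjusted p = 1.33e-04) and for cardiomyocyte 0 of 5 and 3 (median -1.77, adjusted p = 0.0175). Those adjusted over the list alone were 5 and 0, 0 and 4, 0 and 3, with estimated adjusted p = 0.243, 0.243 and 0.455 in that order. Without E12.5 replicate 2 the erythroid, other leukocyte and cardiomyocyte lists gave adjusted p = 0.176, 0.168 and 0.0766, and the leukocyte median was 2.79 with genes at 0 UMIs at their bound. Skeletal muscle markers had a median of -1.21 (adjusted p = 0.0803). Median, mean and test differed in sign for mesenchymal (0.18, -0.03 and down, adjusted p = 0.235), mural (-0.17, 0.29 and down, adjusted p = 0.415), hepatocyte (-0.10, -0.06 and up, adjusted p = 0.647) and chondrocyte markers (-0.04, 0.22 and down, adjusted p = 0.956).

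The second comparison, E15.5 with E12.5, shared a dissection but borrowed the smaller spread of E9.5. Ifitm3, an interferon-inducible membrane gene, rose by 2.10 ± 0.17 (adjusted p = 0.0270), from 155 ± 7.22 to 666 ± 56.3 CPM. Ier3 rose by 2.72 ± 0.28 (adjusted p = 0.0379), the galectin gene Lgals9 by 2.47 ± 0.28 (adjusted p = 0.0448) and the GTPase gene Gem by 2.18 ± 0.22 (adjusted p = 0.0379). These were the 4 genes that met the naming rule among 7 of 12789 genes tested that passed, all of them higher at E15.5. The other 3, named after their values were seen, were Gdf15 at 5.01 ± 0.58, Ifi27l2a at 3.78 ± 0.42 (with 291 CPM in other cells) and the mitochondrial gene mt-Atp8 (adjusted p = 0.0379). Cdh5 was at 1015 ± 22.3 CPM at E15.5 (0.30 ± 0.18, adjusted p = 0.405) and Pecam1 at 512 ± 92.4 (0.39 ± 0.19, adjusted p = 0.329), neither passing. At an unadjusted p below 0.05 stood 2375 genes, and DESeq2 called 592. The count was 0 without E9.5 replicate 1 or 2, where the 4 named genes gave adjusted p = 0.103 and 0.104, 109 without E12.5 replicate 2, 721 without E15.5 replicate 1 and 104 without E15.5 replicate 2. Gdf15, Ifi27l2a and mt-Atp8 lost their calls without either E12.5 library, and Lgals9 (adjusted p = 0.103) without E12.5 replicate 1.

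Over this interval H2-K1 reached 164 ± 23.7 CPM (1.29 ± 0.20, adjusted p = 0.0566), and Ly6c1 and Ly6a were at 2.65 ± 0.34 and 4.05 ± 0.60, short of the threshold over all genes. In the MHC class I and interferon list 1 of 24 rose and 0 fell, 21 and 0 adjusted over the list alone (median 1.86, adjusted p = 5.11e-27, or 0.316 estimated). Vcam1 was at 1.69 ± 0.28, and E-selectin Sele was at 0 UMIs at E12.5 and at least 75.6-fold higher at E15.5. In the leukocyte adhesion list 0 of 15 rose and 0 fell, 8 and 0 adjusted over the list alone (median 0.76, adjusted p = 1.46e-06, or 0.464 estimated). Fabp4 went from 84.5 ± 3.40 to 3901 ± 4617 CPM (5.53 ± 1.01, adjusted p = 0.0701), with 636 CPM in 1 E15.5 library and 7166 in the other. Gpihbp1, which anchors lipoprotein lipase to capillaries, and the fatty-acid transporter gene Cd36 were at 3.02 ± 0.58 and 3.45 ± 0.67. In the lipid handling list 0 of 15 rose and 0 fell, 10 and 0 adjusted over the list alone (median 1.89, adjusted p = 1.46e-08, or 0.464 estimated). Of the early-embryo regulators, Trim71 was at -1.94 ± 0.43 and Igf2bp1 at -1.06 ± 0.25. In the early-embryo and oncofetal list 0 of 13 rose and 0 fell, 0 and 11 adjusted over the list alone (median -1.10, adjusted p = 7.80e-08, or 0.464 estimated). Its median was -1.07 with genes at 0 UMIs at their bound. Cav1 and Fbln5 were at 2.13 ± 0.46 and 1.65 ± 0.27. In the shear stress list 0 of 11 rose and 0 fell, 2 and 0 adjusted over the list alone (median 0.41, adjusted p = 0.0155, or 0.464 estimated). In the basement membrane and matrix list 0 of 22 rose and 0 fell, 4 and 0 adjusted over the list alone (median 0.34, adjusted p = 0.00402, or 0.464 estimated). Without E12.5 replicate 1 the shear and matrix lists gave adjusted p = 0.084 and 0.118.

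Of stress-response genes, Zfp36, Atf3 and Hspa1a were at 2.00 ± 0.31, 2.53 ± 0.42 and 4.26 ± 0.53, the last with a close paralog. In the dissociation stress list 1 of 20 rose and 0 fell, 12 and 0 adjusted over the list alone (median 1.27, adjusted p = 3.60e-16, or 0.372 estimated). The macrophage receptor gene Mrc1 was at 1.64 ± 0.31. For E15.5 against E12.5, 0 of 10 macrophage markers rose and 0 fell, 4 and 0 adjusted over the list alone (median 0.69, adjusted p = 6.07e-04, or 0.464 estimated). Among pericyte and smooth muscle genes, 0 of 8 mural markers rose and 0 fell, 2 and 0 adjusted over the list alone (median 0.89, adjusted p = 0.0416, or 0.464 estimated), a call that gave adjusted p = 0.229 without E12.5 replicate 1 and 0.0563 without E15.5 replicate 1. The neuronal gene Tubb3 was at -3.42 ± 0.46. For neurons, 0 of 6 neural markers rose and 0 fell, 0 and 2 adjusted over the list alone (median -0.50, adjusted p = 0.00117, or 0.372 estimated). In heart muscle, 0 of 5 cardiomyocyte markers rose and 0 fell, 0 and 2 adjusted over the list alone (median -2.15, adjusted p = 0.00274, or 0.464 estimated), with adjusted p = 0.108 without E15.5 replicate 2. In cartilage, 0 of 3 chondrocyte markers rose and 0 fell, 0 and 2 adjusted over the list alone (median -1.40, adjusted p = 0.0145, or 0.464 estimated), and this gave adjusted p = 0.169, 0.177, 0.789 and 0.506 without E9.5 replicate 1 or 2, E12.5 replicate 2 and E15.5 replicate 2. In the S phase list 0 of 30 rose and 0 fell, also adjusted over the list alone (median -0.21, adjusted p = 0.0197, or 0.764 estimated). That call gave adjusted p = 0.712 without E15.5 replicate 1. Cox5b was at 0.77 ± 0.19. In the oxidative phosphorylation list 0 of 26 rose and 0 fell, also adjusted over the list alone (median 0.31, adjusted p = 0.0145, or 0.764 estimated). It gave adjusted p = 0.949, 0.0756 and 0.0931 without E12.5 replicate 2, E15.5 replicate 1 or 2.

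Among lists that did not pass between E12.5 and E15.5, Bsg of the barrier list was at 827 ± 72.0 CPM against 424 ± 39.6 (adjusted p = 0.0819), while Lef1 and Foxq1, Wnt targets, were at -0.97 ± 0.21 and -1.39 ± 0.40. Medians were -0.20 (adjusted p = 0.171) for blood-brain barrier genes, -0.41 (adjusted p = 0.0751) for Wnt response, 0.17 (adjusted p = 0.164) for arterial and Notch genes, 0.14 (adjusted p = 0.926) for VEGF and tip-cell genes and 0.24 (adjusted p = 0.0691) for BMP and TGF-beta genes. The endocardial gene Hapln1 was at -1.22 ± 0.26, and its list gave -0.44 (adjusted p = 0.208). The venous list gave a median of -0.02 with a mean of 0.59 and a test pointing down (adjusted p = 0.609), and the lymphatic list a median of -0.23 with a mean of 0.13 and a test pointing up (adjusted p = 0.809). Glycolysis and hypoxia genes gave 0.17 (adjusted p = 0.538), G2 and M phase genes -0.09 (adjusted p = 0.212), imprinted growth genes -0.13 (adjusted p = 0.171), and Hox groups 1 to 5 and 6 to 13 0.23 (adjusted p = 0.212) and -0.24 (adjusted p = 0.438). Adjusted over the list alone, at most 4 genes of a list that did not pass rose and at most 3 fell. Erythroid markers had a median of 0.24, a mean of -0.09 and a test pointing up (adjusted p = 0.851). The remaining marker lists gave 0.36 (adjusted p = 0.639) for megakaryocyte, 0.55 (adjusted p = 0.197) for other leukocyte, 0.29 (adjusted p = 0.683) for mesenchymal, -0.89 (adjusted p = 0.0991) for epithelial, -0.02 (adjusted p = 0.922) for skeletal muscle and -0.31 (adjusted p = 0.171) for hepatocyte genes.

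**Figure D3:**
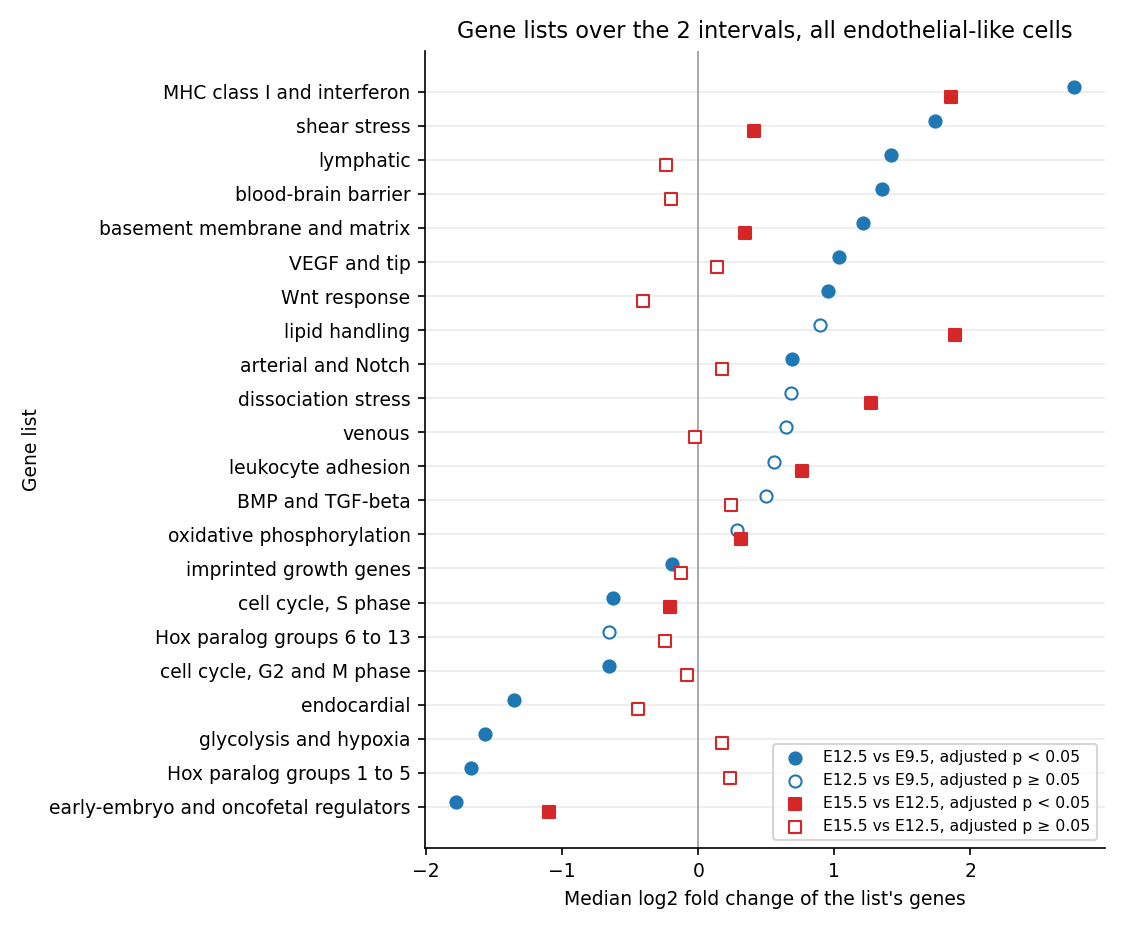
Median log2 change of each of 22 gene lists (horizontal axis) from E9.5 to E12.5 (circles) and from E12.5 to E15.5 (squares) in all endothelial-like cells, filled where the camera test with a preset correlation gave an adjusted p below 0.05. MHC class I and interferon genes were higher at the later stage in both intervals (2.76 and 1.86) and early-embryo regulators lower (-1.78 and -1.10), and no list passed with an estimated correlation.

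Across the whole interval, E15.5 against E9.5, the same early regulators had almost disappeared from endothelium. Lin28a was at 0 UMIs at E15.5, at least 533-fold lower, Etv2 was 2033-fold (interval 562 to 16800) lower and Sall4 513-fold (interval 142 to 4248) lower. Cyp26a1 and Phlda2 fell by 6.98 ± 0.57 and 6.87 ± 0.44. Fabp4 rose by 13.86 ± 1.54 (adjusted p = 4.91e-04), and Rgcc, a cell-cycle and complement-response gene, by 8.44 ± 0.47, from 1.29 ± 0.438 to 444 ± 151 CPM. Eln was 1761-fold (interval 487 to 14550) higher and Fbln5 at least 863-fold higher. The sodium-channel gene Scn7a was at least 458-fold higher, and Sult1a1, Fbxl7 and Ifi27 were 1238-fold (interval 222 to 48900), 851-fold (interval 291 to 4130) and 854-fold (interval 153 to 33750) higher. Cma1, Cxcl2 and F13a1 also ranked among the largest rises (at least 654-fold, 1060-fold (interval 190.0 to 41890) and 396-fold (interval 109 to 3271)), but non-endothelial cells of the E15.5 libraries held 4526, 919 and 745 CPM of them. Ccl21a, with its paralogs, was at least 3590-fold higher. Ece2, Hgs, Fdx1l, Commd5 and Pelo, which overlap genes of the later table only, were lower (1061-fold (interval 293 to 8769), 938-fold (interval 168 to 37120), and falls by 9.11 ± 0.37, 6.84 ± 0.51 and 6.29 ± 0.26). Pecam1 rose by 2.11 ± 0.20 (adjusted p = 2.37e-04) and Cdh5 by 1.48 ± 0.18 (adjusted p = 7.56e-04). Of 12789 genes 5298 passed, 2935 higher and 2363 lower at E15.5. The count was 2732 without E9.5 replicate 1 and 2289 without E9.5 replicate 2. In the same order Cma1 gave adjusted p = 0.0666 and 0.0802, and Cxcl2 gave 0.0657 without E9.5 replicate 2.

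Over this span H2-K1 rose by 4.65 ± 0.24 (adjusted p = 2.70e-05), Ifitm3 by 2.74 ± 0.18 and Ly6c1 by 5.80 ± 0.43, against a fall of Ifitm1 by 3.41 ± 0.43. Cav1, the main caveolar coat gene, rose by 7.02 ± 0.58, from 7.71 ± 3.03 to 1005 ± 676 CPM, and Gpihbp1 and Meox2 by 6.16 ± 0.69 and 6.73 ± 0.65. For MHC class I and interferon 21 of 24 rose and 1 fell (median 4.58, adjusted p = 9.55e-14), for shear stress 10 of 11 and 0 (median 1.88, adjusted p = 5.44e-06) and for lipid handling 10 of 15 and 1 (median 3.19, adjusted p = 2.26e-04). Such counts adjusted over the list alone were 21 and 1, 10 and 0, 11 and 1, with estimated adjusted p = 0.186, 0.186 and 0.356 in that order. Jam2 and Vcam1 rose by 7.73 ± 0.50 and 4.83 ± 0.39, and Col15a1 by 4.32 ± 0.37, while Fn1 fell by 1.54 ± 0.27, but with equal numbers of arterial cells per library Fn1 and Ifitm1 were at 0.52 and 0.11. Slc38a3 and Mfsd2a rose by 4.48 ± 0.26 and 7.04 ± 0.55, and Slc16a1 fell by 1.65 ± 0.19. For leukocyte adhesion 12 of 15 rose and 2 fell (median 1.08, adjusted p = 2.26e-04), for matrix genes 15 of 22 and 2 (median 1.63, adjusted p = 2.69e-09) and for blood-brain barrier genes 17 of 26 and 1 (median 1.37, adjusted p = 1.55e-06). Counts adjusted over the list alone were 12 and 3, 15 and 2, 17 and 1, with estimated adjusted p = 0.310, 0.219 and 0.310 in that order. Robo4 and Jag2 rose by 4.52 ± 0.22 and 3.61 ± 0.33, Hey1 fell by 1.17 ± 0.22, Reln rose by 2.03 ± 0.25 and Foxc2 fell by 3.18 ± 0.27. For arterial and Notch 14 of 22 rose and 1 fell (median 0.94, adjusted p = 1.23e-04), for VEGF and tip-cell 11 of 20 and 0 (median 0.98, adjusted p = 1.63e-05) and for lymphatic 7 of 12 and 1 (median 1.61, adjusted p = 0.00977). They were, adjusted over the list alone, 16 and 2, 11 and 0, 7 and 1, with estimated adjusted p = 0.186, 0.195 and 0.403 in that order. Zfp36 rose by 4.35 ± 0.35, Ndufa1 by 2.00 ± 0.25 and Bmp6 by 4.47 ± 0.55, and Hsp90aa1 fell by 1.17 ± 0.19. For dissociation stress 16 of 20 rose and 1 fell (median 3.03, adjusted p = 6.99e-07), for oxidative phosphorylation 8 of 26 and 0 (median 0.40, adjusted p = 0.0284) and for BMP and TGF-beta genes 10 of 17 and 4 (median 0.67, adjusted p = 0.0498). Adjusted over the list alone, they were 16 and 1, 8 and 0, 10 and 4, with estimated adjusted p = 0.241, 0.639 and 0.390 in that order. The respiratory list gave adjusted p = 0.0669, 0.0640 and 0.0789 without E9.5 replicate 1, E15.5 replicate 1 or 2, and the BMP and TGF-beta list 0.148, 0.116 and 0.0961 without E9.5 replicate 2, E15.5 replicate 1 or 2.

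Lists that were lower at E15.5 than at E9.5 included glycolysis and the early-embryo regulators. Slc16a3 and Ldha fell by 4.43 ± 0.30 and 1.85 ± 0.20, Ldha from 2491 ± 41.8 to 689 ± 67.9 CPM, while Pgk1 rose by 1.42 ± 0.18. Trim71 fell by 5.18 ± 0.44, Igf2 by 5.64 ± 0.53 and Uhrf1 by 1.63 ± 0.18, and Gnas rose by 2.38 ± 0.20. For glycolysis and hypoxia 3 of 22 rose and 14 fell (median -1.56, adjusted p = 7.08e-07), for early-embryo and oncofetal genes 0 of 13 and 13 (median -3.01, adjusted p = 9.55e-14) and for imprinted genes 2 of 18 and 10 (median -0.96, adjusted p = 0.00298). Those adjusted over the list alone were 4 and 14, 0 and 13, 2 and 10, with estimated adjusted p = 0.186, 0.241 and 0.219 in that order. In the cell cycle and heart lists, for S phase 0 of 30 rose and 21 fell (median -0.86, adjusted p = 5.19e-07), for G2 and M phase 0 of 30 and 20 (median -0.68, adjusted p = 3.72e-05) and for endocardial genes 2 of 16 and 8 (mean -1.09, adjusted p = 0.00257). Such counts adjusted over the list alone were 0 and 21, 1 and 22, 2 and 10, with estimated adjusted p = 0.310, 0.390 and 0.390 in that order. Hoxb5 and Hoxc9 fell by 1.72 ± 0.22 and 5.78 ± 0.54, and Hoxd8 and Hoxd10 rose by 2.01 ± 0.41 and 2.92 ± 0.64. For Hox groups 1 to 5 1 of 12 rose and 7 fell (median -1.55, adjusted p = 0.00329) and for groups 6 to 13 2 of 14 and 7 (median -1.30, adjusted p = 0.0498). Counts adjusted over the list alone were 2 and 8, 3 and 7, with estimated adjusted p = 0.310 and 0.616 in that order. Groups 6 to 13 had a median of 1.34 with equal numbers of arterial cells, and gave adjusted p = 0.528 and a median of 0.38 without E9.5 replicate 2, and 0.0641, 0.0580 and 0.0595 without E12.5 replicate 1 or 2 and E15.5 replicate 1. Venous and Wnt-response lists did not pass (medians 0.54 and 0.42, adjusted p = 0.268 and 0.0927). Aplnr rose by 1.21 ± 0.17, but was at -2.07 with equal numbers of arterial cells.

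Transcripts of other cell types in the E15.5 sums differed from E9.5 in both directions. C1qb was 617-fold (interval 110.5 to 24390) higher and Pf4 rose by 5.05 ± 0.39, while Krt8 fell by 7.64 ± 0.37 and Actc1 by 4.39 ± 0.49. For macrophage 10 of 10 rose and 0 fell (median 8.97, adjusted p = 8.10e-12), for megakaryocyte 4 of 5 and 1 (median 4.11, adjusted p = 0.0251) and for other leukocyte markers 6 of 10 and 0 (median 6.31, adjusted p = 0.0228). They were, adjusted over the list alone, 10 and 0, 4 and 1, 6 and 0, with estimated adjusted p = 0.219, 0.259 and 0.507 in that order. With genes at 0 UMIs at their bound the macrophage and leukocyte medians were 5.35 and 3.41, and without E15.5 replicate 2 the leukocyte list gave adjusted p = 0.0514. Embryonic globin Hbb-bh1 was 1561-fold (interval 534 to 7574) lower while adult Hbb-bs rose by 5.95 ± 0.90. For erythroid 2 of 11 rose and 5 fell (median -2.66, adjusted p = 0.0487), for epithelial 0 of 5 and 4 (median -4.35, adjusted p = 4.45e-05) and for cardiomyocyte markers 0 of 5 and 5 (median -3.16, adjusted p = 5.62e-04). Adjusted over the list alone, they were 2 and 6, 0 and 5, 0 and 5, with estimated adjusted p = 0.310, 0.186 and 0.310 in that order. The epithelial median was -3.72 at the bound, and the erythroid list gave adjusted p = 0.0630, 0.154 and 0.0961 without E9.5 replicate 1, E15.5 replicate 1 or 2. Lists that did not pass were skeletal muscle (median -1.29, adjusted p = 0.0927), chondrocyte (-1.45, adjusted p = 0.221), neural (1.62, adjusted p = 0.414), mural (0.80, adjusted p = 0.863) and hepatocyte (-0.41, adjusted p = 0.866). Mesenchymal markers had a median of 0.40, a mean of 0.20 and a test pointing down (adjusted p = 0.351).

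To ask whether these changes also held within 1 kind of vessel, the comparisons were repeated within named classes with at least 30 cells in each library compared. The cells of some classes lay in different clusters at different stages. Arterial cells filled 1 cluster at E9.5 (149 and 144 cells per library), another 2 at E12.5 (115 and 151, and 99 and 109) and mostly the second of these at E15.5 (5 and 1, and 87 and 112). Endocardial and venous cells of E9.5 lay in clusters without later cells. A change within such a class can thus be one of its make-up. In arterial cells from E9.5 to E12.5, Fbln5 was at least 353-fold higher, Eln 1666-fold (interval 299 to 65850) higher and Mgp 666-fold (interval 119 to 26350) higher. Gkn3 and Rtp4, at 0 UMIs at E9.5, were at least 100.4-fold and at least 37.4-fold higher. Lin28a was at least 47.9-fold lower, Cyp26a1 227-fold (interval 77.4 to 1105) lower, and Tonsl fell by 6.95 ± 0.45. For S phase 0 of 30 rose and 28 fell (median -1.50, adjusted p = 5.15e-17), for G2 and M phase 0 of 30 and 28 (median -1.86, adjusted p = 8.29e-25), for glycolysis and hypoxia 1 of 21 and 13 (median -1.59, adjusted p = 4.01e-08) and for early-embryo regulators 0 of 12 and 8 (median -1.92, adjusted p = 3.25e-10). Those adjusted over the list alone were 0 and 28, 0 and 29, 2 and 13, 0 and 9, with estimated adjusted p = 0.206, 0.247, 0.247 and 0.172 in that order. For arterial and Notch 13 of 20 rose and 0 fell (median 1.03, adjusted p = 2.89e-09), for matrix genes 14 of 22 and 0 (median 1.24, adjusted p = 3.49e-12) and for MHC class I and interferon 11 of 19 and 1 (median 1.81, adjusted p = 6.57e-06). Such counts adjusted over the list alone were 14 and 0, 16 and 2, 11 and 1, with estimated adjusted p = 0.206, 0.206 and 0.206 in that order. In all, 2479 genes passed, 1374 higher and 1105 lower, against 1278 without E9.5 replicate 1 and 797 without E9.5 replicate 2.

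From E12.5 to E15.5 in arterial cells the potassium-channel subunit gene Kcne3 fell by 4.14 ± 0.46 (adjusted p = 8.74e-04), from 119 to 6.27 CPM, the mechanosensitive channel gene Piezo2 by 3.55 ± 0.45, Mycn by 3.47 ± 0.50, Mmrn1 by 3.32 ± 0.46 and the apelin receptor gene Aplnr by 2.85 ± 0.45. Ifi27l2a rose by 5.06 ± 0.55 (adjusted p = 8.74e-04), the retinol-binding gene Rbp7 by 5.41 ± 0.81, and the chemokine genes Cxcl1 and Ccl7 by 4.42 ± 0.48 and 4.30 ± 0.60 (Ifi27l2a and Ccl7 also led the unnamed cluster with all macrophage markers), and the detoxifying gene Ephx1 was 56.1-fold (interval 14.9 to 473) higher. Rbp7 gave adjusted p = 0.0503 without E12.5 replicate 2. Ly6a and Cd36, at 4.73 ± 0.89 and 4.40 ± 0.88, lost their calls without E12.5 replicate 1 (adjusted p = 0.0812 and 0.0812), E12.5 replicate 2 (0.0817 and 0.0514) or E15.5 replicate 2 (0.363 and 0.432). For MHC class I and interferon 13 of 19 rose and 0 fell (median 1.56, adjusted p = 3.98e-17), for arterial and Notch 5 of 20 and 0 (median 0.56, adjusted p = 2.20e-06) and for BMP and TGF-beta 3 of 16 and 0 (median 0.70, adjusted p = 6.78e-06). Counts adjusted over the list alone were 15 and 0, 9 and 1, 8 and 0, with estimated adjusted p = 0.0766, 0.164 and 0.199 in that order. For VEGF and tip-cell 2 of 19 rose and 6 fell (median -0.09, adjusted p = 0.00583) and for venous genes 1 of 8 and 4 (median -1.10, adjusted p = 0.0453). They were, adjusted over the list alone, 2 and 7, 2 and 4, with estimated adjusted p = 0.285 and 0.634 in that order. For dissociation stress 13 of 20 rose and 0 fell (median 1.57, adjusted p = 3.65e-20) and for macrophage markers 6 of 9 and 0 (median 2.17, adjusted p = 7.50e-15). Adjusted over the list alone, they were 16 and 0, 9 and 0, with estimated adjusted p = 0.164 and 0.164 in that order. A total of 504 genes passed, 332 higher and 172 lower, against 315, 332, 293 and 196 without E9.5 replicate 1 or 2, E12.5 replicate 1 and E15.5 replicate 2.

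Between E9.5 and E15.5 arterial Fbln5 was at least 1731-fold higher, Fabp4 3427-fold (interval 948 to 28300) higher and the matrix cross-linking gene Lox at least 107-fold higher. Hsd11b2, Pcsk1n and Edil3 were at least 26.2-fold, at least 20.5-fold and at least 19.9-fold lower. All 12 early-embryo regulators tested fell (median -3.53, adjusted p = 2.67e-13, or 0.255 estimated), as did 30 of 30 G2 and M phase genes (median -2.30, adjusted p = 1.89e-21, or 0.256 estimated), and of MHC class I and interferon genes 16 of 19 rose and 0 fell, also adjusted over the list alone (median 4.76, adjusted p = 1.57e-14, or 0.203 estimated). Arterial cells gave 3367 genes, 1822 higher and 1545 lower, against 2219, 1690 and 2214 without E9.5 replicate 1 or 2 and E15.5 replicate 2. In endocardial cells from E9.5 to E12.5, Pthlh, a parathyroid-hormone-related peptide gene, was at least 127-fold higher, the protease gene Adamts8 at least 71.0-fold higher and Wnt9b, which acts in valve formation, at least 29.4-fold higher. Sall4 and Lin28a were at least 10.0-fold and at least 11.9-fold lower. For shear-stress genes 9 of 11 rose and 0 fell, also adjusted over the list alone (median 1.31, adjusted p = 1.69e-09, or 0.345 estimated), and for glycolysis and hypoxia genes 1 of 21 rose and 15 fell, also adjusted over the list alone (median -1.59, adjusted p = 4.61e-10, or 0.345 estimated). Endocardium gave 2370 genes, 1296 higher and 1074 lower, against 1111 and 925 without E9.5 replicate 1 or 2. In venous cells from E9.5 to E15.5, Igfbp7 was 9870-fold (interval 1770 to 390000) higher, Ccl2, which also led that macrophage-marker cluster, at least 345-fold higher, and Etv2 and Sfrp2 at least 52.9-fold and at least 26.2-fold lower. Venous cells gave 4028 genes, 2208 higher and 1820 lower, but 863 without E9.5 replicate 2 and, by edgeR, 0 without E9.5 replicate 1, where these 4 genes gave adjusted p = 0.0912, 0.104, 0.0662 and 0.0746 and 2568 genes stood at an unadjusted p below 0.05.

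Brain-like cells could be compared between E12.5 and E15.5. The stress gene Ier3 rose by 3.39 ± 0.25 (adjusted p = 0.00262), and the interferon-response factor gene Irf1 by 3.16 ± 0.44. Lgals9 rose by 3.03 ± 0.36 and Fgfbp1 by 2.85 ± 0.40, and Hapln1 fell by 3.65 ± 0.52. The paralogs Hspa1a and Hspa1b, which share most of their sequence, rose by 5.11 ± 0.52 and 4.66 ± 0.64. Blood-brain barrier genes gave 0 rises of 25 over all genes and 5 adjusted over the list alone (median 0.62, adjusted p = 7.77e-07, or 0.557 estimated), and MHC class I and interferon genes 2 of 18 and 14 (median 1.53, adjusted p = 3.49e-23, or 0.211 estimated). Only 16 genes passed, 15 higher, and the count was 1 without E12.5 replicate 1, 0 without E12.5 replicate 2 by edgeR (984 genes at an unadjusted p below 0.05), 195 without E15.5 replicate 1 and 130 without E15.5 replicate 2. Without E12.5 replicate 2, Ier3, Irf1, Lgals9, Fgfbp1 and Hapln1 gave adjusted p = 0.0602, 0.207, 0.113, 0.198 and 0.176, and of these only Ier3 held without E12.5 replicate 1. In lymphatic cells over the same interval the growth-differentiation factor gene Gdf15 was 299-fold (interval 53.0 to 11850) higher, Clec2d rose by 4.09 ± 0.47 (adjusted p = 0.0127), Fgl2 by 5.16 ± 0.87 and Ifitm3 by 4.08 ± 0.67, from 25.1 to 423 CPM, and Meg3 fell by 1.61 ± 0.30. Lymphatic-identity genes gave 1 rise of 12 and 7 adjusted over the list alone (median 0.85, adjusted p = 4.18e-05, or 0.301 estimated), and shear-stress genes 3 of 7 and 7 (median 2.12, adjusted p = 6.07e-10, or 0.301 estimated). The lymphatic count was 89 genes, 82 higher, and 25, 7, 541 and 145 without E12.5 replicate 1 or 2, E15.5 replicate 1 or 2. Without E12.5 replicate 2, Gdf15, Clec2d, Fgl2, Ifitm3 and Meg3 gave adjusted p = 0.139, 0.0891, 0.242, 0.236 and 0.150, and the last 3 also lost their calls without E12.5 replicate 1.

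Whether brain-like cells changed differently from other endothelium between E12.5 and E15.5 was tested directly, with a class-by-stage term. Bsg, which chaperones monocarboxylate transporters at the blood-brain barrier, went from 636 to 4504 CPM in brain-like cells and from 380.4 to 487 in the others (difference of log2 changes 2.36 ± 0.34, adjusted p = 0.0270). The tight-junction gene Cldn5 went from 1653 to 3775 CPM in brain-like cells and from 637 to 691 in the others (1.02 ± 0.12, adjusted p = 0.00991), and the heparan-sulphate enzyme gene Hs3st1 from 22.7 to 79.9 CPM in brain-like cells and from 25.1 to 29.2 in the others (1.56 ± 0.19, adjusted p = 0.00991). The others were not the same clusters at both stages, with 721 and 701 cells in 2 unnamed clusters mostly of E12.5 and 800 and 682 in 2 capillary clusters mostly of E15.5, so a difference can come from their make-up. Another 2 genes differed the other way. Hapln1, a hyaluronan-link gene, went from 63.8 to 4.65 CPM in brain-like cells and from 69.1 to 31.4 in the others (-2.52 ± 0.35, adjusted p = 0.0230), and S100a10, which binds plasminogen at the cell surface, from 119 to 73.7 CPM in brain-like cells and from 369 to 993 in the others (-2.00 ± 0.24, adjusted p = 0.00991). Of 26 blood-brain barrier genes 2 passed and 19 did so adjusted over the list alone, toward brain-like cells (median 0.91, adjusted p = 9.37e-20, or 0.694 estimated). In all 9 genes passed, 7 with a positive and 2 with a negative difference, and 3 of them were globin genes, which the naming rule leaves out. Each of the 5 named genes passed on leaving out any 1 of the 4 libraries, although the count was 121, 51 and 350 without E12.5 replicate 1 or 2 and E15.5 replicate 1. Lists that also passed toward brain-like cells were dissociation stress (median 0.37, adjusted p = 2.19e-06), glycolysis and hypoxia (0.27, adjusted p = 3.46e-04) and erythroid markers (2.17, adjusted p = 2.47e-13). Away from them passed S phase (-0.24, adjusted p = 4.88e-04), G2 and M phase (-0.29, adjusted p = 2.19e-06), matrix (-0.46, adjusted p = 1.09e-04), Hox groups 1 to 5 (-1.60, adjusted p = 0.00328) and 6 to 13 (-0.64, adjusted p = 0.0204) and mural markers (adjusted p = 0.0157). None passed with an estimated correlation or by fry.

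Classes were compared with the other endothelial-like cells of the same libraries for 12 lists whose genes had not been used in clustering. Arterial cells expressed more of the matrix genes Mgp and Eln, by 5.01 ± 0.35 and 6.03 ± 0.47, and more H2-D1 and Isg15, by 1.31 ± 0.09 and 2.36 ± 0.19. In arterial cells, for matrix genes 15 of 22 higher and 1 lower (median 0.79, adjusted p = 1.87e-10), for MHC class I and interferon 11 of 20 and 1 (median 0.61, adjusted p = 1.08e-05), for leukocyte adhesion 6 of 12 and 3 (median 0.49, adjusted p = 0.00442) and for dissociation stress 7 of 20 and 2 (median 0.50, adjusted p = 0.00430). Those adjusted over the list alone were 16 and 1, 12 and 1, 7 and 3, 9 and 2, with estimated adjusted p = 0.0312, 0.142, 0.341 and 0.341 in that order. For S phase 0 of 30 higher and 28 lower (median -0.86, adjusted p = 2.06e-12), for G2 and M phase 0 of 30 and 28 (median -1.07, adjusted p = 1.84e-12), for glycolysis and hypoxia 1 of 21 and 9 (median -0.19, adjusted p = 0.00892) and for oxidative phosphorylation 0 of 26 and 6 (median -0.18, adjusted p = 0.00430). Such counts adjusted over the list alone were 0 and 30, 0 and 30, 1 and 10, 0 and 6, with estimated adjusted p = 0.341, 0.341, 0.413 and 0.582 in that order. Endocardial cells expressed more of the imprinted genes Igf2r and Cdkn1c, by 2.57 ± 0.11 and 3.14 ± 0.13, while the glucose transporter gene Slc2a1 was at -2.97 ± 0.26 and Hoxd8 at -5.11 ± 0.44 relative to the rest. In endocardial cells, for imprinted genes 7 of 17 higher and 3 lower (median 0.59, adjusted p = 7.83e-06), for glycolysis and hypoxia 0 of 21 and 18 (median -0.80, adjusted p = 1.56e-11) and for Hox groups 6 to 13 0 of 9 and 9 (median -2.82, adjusted p = 5.14e-10). Counts adjusted over the list alone were 7 and 3, 0 and 18, 0 and 9, with estimated adjusted p = 0.0411, 0.0177 and 0.127 in that order. Further, for Hox groups 1 to 5 0 of 7 higher and 4 lower (median -1.58, adjusted p = 0.00354), for G2 and M phase 0 of 30 and 11 (median -0.41, adjusted p = 1.62e-05) and for oxidative phosphorylation 0 of 26 and 4 (median -0.24, adjusted p = 0.00290). They were, adjusted over the list alone, 0 and 6, 0 and 17, 0 and 4, with estimated adjusted p = 0.332, 0.316 and 0.627 in that order. The arterial matrix list and the endocardial imprinted and glycolysis lists thus passed with an estimated correlation too.

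In brain-like cells the positional genes Hoxa5 and Hoxd8 were at -3.43 ± 0.25 and -2.13 ± 0.15 relative to the rest, the imprinted genes Gnas and Peg3 at -1.45 ± 0.08 and -2.29 ± 0.23, and Eln at -5.68 ± 0.28, while the basement-membrane gene Agrn was at 1.43 ± 0.14. In brain-like cells, for Hox groups 1 to 5 0 of 8 higher and 7 lower (median -1.76, adjusted p = 1.15e-05), for Hox groups 6 to 13 0 of 10 and 9 (median -1.77, adjusted p = 1.05e-06) and for imprinted genes 1 of 16 and 10 (median -0.91, adjusted p = 1.97e-06). Adjusted over the list alone, they were 0 and 7, 0 and 10, 1 and 12, with estimated adjusted p = 0.251, 0.251 and 0.143 in that order. For matrix genes 4 of 22 higher and 10 lower (median -0.20, adjusted p = 4.95e-04) and for S phase 0 of 30 and 5 (median -0.23, adjusted p = 0.0155). Those adjusted over the list alone were 5 and 11, 0 and 3, with estimated adjusted p = 0.625 and 0.927 in that order. In lymphatic cells the junction gene Esam was at -5.92 ± 0.16 and Cd47 at 1.84 ± 0.13, Col4a1 and Sparc at -1.81 ± 0.11 and -2.34 ± 0.09, Ly6c1 at -4.39 ± 0.44 and Ier3 at -2.38 ± 0.14. In lymphatic cells, for leukocyte adhesion 1 of 12 higher and 5 lower (median -0.99, adjusted p = 1.35e-05), for matrix genes 3 of 22 and 12 (median -0.98, adjusted p = 1.88e-07), for MHC class I and interferon 0 of 22 and 10 (median -0.78, adjusted p = 3.08e-04) and for dissociation stress 1 of 20 and 15 (median -0.82, adjusted p = 1.88e-07). Such counts adjusted over the list alone were 1 and 6, 3 and 13, 1 and 10, 1 and 16, with estimated adjusted p = 0.193, 0.269, 0.193 and 0.193 in that order. Venous cells had more Ackr1, the venular chemokine receptor gene of the venous marker list, by 1.96 ± 0.26, and Icam1, by 0.98 ± 0.15. In venous cells, for leukocyte adhesion 2 of 12 higher and 0 lower (median 0.02, adjusted p = 0.0405), for S phase 0 of 30 and 0 (median -0.33, adjusted p = 2.41e-08) and for G2 and M phase 0 of 30 and 0 (median -0.33, adjusted p = 2.41e-08). Counts adjusted over the list alone were 2 and 0, 0 and 0, 0 and 0, with estimated adjusted p = 0.519, 0.519 and 0.519 in that order. For oxidative phosphorylation 0 of 26 higher and 0 lower (median -0.17, adjusted p = 4.79e-04), for Hox groups 1 to 5 0 of 9 and 0 (median 0.47, adjusted p = 0.00270) and for Hox groups 6 to 13 0 of 9 and 0 (median -0.47, adjusted p = 0.00133). They were, adjusted over the list alone, 0 and 0, 2 and 0, 0 and 1, with estimated adjusted p = 0.645, 0.519 and 0.519 in that order. Lists not given for a class did not pass there.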

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

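The tests of the MHC and early-embryo lists over the E12.5 to E15.5 interval were chosen after the result was seen. Differences between groups drew attention to 5 genes with a class-by-stage term in brain-like cells, S100a10 (-2.00), Hs3st1 (1.56), Bsg (2.36), Hapln1 (-2.52) and Cldn5 (1.02). Counts not used in any comparison, on genes in a single gene table, were highest in E15.5 replicate 2, at 0.238% of its UMIs.

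MHC class I and interferon genes were higher in endothelial-like cells at E15.5 than at E9.5. RNA of cells named macrophage would need to supply at least 50% of the median member's signal, but supplied at most 1.853%. Single members reached 41.38% and 17.15% in E15.5 replicate 1 and 2. Other leukocytes and unnamed macrophage-marker clusters were not tested. Arterial cells, at 103.9% of the list median over all cells, argue against another mix of classes. They lay in different clusters at the 2 stages, so their make-up stays open. The E9.5 dissection and gene table would leave no change after E12.5, but the E12.5 to E15.5 median was 1.86. They could add to the earlier rise. Stage itself was not tested.

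The lipid-handling median rose from E12.5 to E15.5 (0 of 15 passed). Another mix of endothelial classes could be the source of much of this, since within the arterial, brain-like and lymphatic classes the list median was at most 48.05% of that over all cells, close to the 50% set as the bound. RNA of cells named macrophage supplied at most 0.3907% of the median member's signal. Single members reached 61.22% and 5.605% in E15.5 replicate 1 and 2. A stage change in capillaries stays open and was not tested.

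Early-embryo and oncofetal regulators were lower at E15.5 than at E9.5. RNA from other cells at E9.5 would carry these genes and other cells' markers alike, but the ratio of endothelial to other-cell CPM was 15.97 times as high for the regulators, or more. Another mix of classes is argued against by arterial cells, where the median was 117.2% of that over all cells, with the same limit on clusters. Dissection and gene table alone would leave no fall after E12.5, but the median was -1.10 from E12.5 to E15.5. Stage itself remains open, as does a part for dissection in the earlier fall.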

How the results depend on the processing

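Some alternatives, named under processing, were added after the data were seen. With 2 libraries per stage most counts of genes depended on single libraries, and no gene list passed with an estimated correlation in any stage contrast (0, 0 and 0 lists, against 22, 14 and 26). The cause was not tested for any value below.

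E15.5 against E12.5 gave 7 genes, but 23 with RLE normalization, 592 with DESeq2, 1344 without the filter, 0 with only the compared stages in the fit, 4 with doublets kept, 41 with the stricter cell filter, 86 with equal and thinned cells, 349 with equal numbers of arterial cells per library (equal arterial cells), 60 with the robust spread, 40 with mixed clusters kept, 4 without genes far higher in other cells, 10 with the gate on own counts (3 of the 7 among them), and 0 to 721 on leaving out 1 library. With the replicate number as a block (replicate block) it gave 61. Replicate numbers do not pair libraries, as correlations of their deviations were -0.09, 0.06 and 0.03 over 7767 genes. E12.5 against E9.5 gave 4271 genes, 2825 with the stricter filter, 1696 with equal arterial cells and 1268 to 4707 on leaving out 1 library. E15.5 against E9.5 gave 5298 genes, 2834 with equal arterial cells and 2289 to 6024 on leaving out 1 library.

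Within classes, arterial E15.5 against E12.5 gave 504 genes, 1003 without the filter, 211 with doublets kept and 196 to 614 on leaving out 1 library. Arterial E12.5 against E9.5 gave 797 to 2764 and E15.5 against E9.5 1690 to 3881 over left-out libraries. Brain-like cells gave 16 genes, 7 with RLE, 381 without the filter, 2 with the replicate block and 0 to 195 over left-out libraries. Endocardial counts ranged from 925 to 3143 and venous counts from 0 to 5469. Lymphatic cells gave 89 genes, 537 without the filter, 30 with the replicate block and 7 to 541 over left-out libraries. The class-by-stage term gave 9 genes, 212 without the filter, 3 with the robust spread and 13 to 350 over left-out libraries.

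With equal arterial cells, 14 and 14 lists passed for E12.5 and E15.5 against E9.5. With an estimated correlation 1, 0, 2, 0 and 0 lists separated arterial, brain, endocardial, lymphatic and venous cells from the rest, and lymphatic cells ranged from 4 to 7 over left-out libraries. Lists whose test pointed the other way, though not always their median, were lymphatic (medians 0.0729 and -1.09 with equal arterial cells, E12.5 and E15.5 against E9.5), oxidative phosphorylation from E12.5 to E15.5 (0.0650 with equal arterial cells, and from 0.0599 to 0.578 over left-out libraries) and Hox groups 6 to 13 from E9.5 to E15.5 (1.34 with equal arterial cells). Trends of shares that turned or came to 0 were megakaryocyte (rho = 0 with doublets kept), mesenchymal and neural (0 and -0.717 with the stricter filter), arterial and venous (0.606 and 0.606 in cells thinned to 2000 UMIs) and sinusoidal (0.956 at resolution 0.5). Genes that reversed with equal arterial cells were Trp53i11 from E12.5 to E15.5 (-1.55) and, from E9.5 to E15.5, Foxq1 (-0.90), Aplnr (-2.07), Nrp2 (-1.15), Tmem100 (0.11), Smad6 (1.55), Fn1 (0.52), Ifitm1 (0.11) and Notch3 (0.00647). With mixed clusters kept Notch3 was at 0.0312 and Prrx1 at 0.33, and with equal and thinned cells Col1a1 was at -0.11, in the same interval.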

Other observations

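No test in this part was run beyond the values given. Several endothelial clusters had no expression test of their own. At E9.5 a group of 11 cells, 8 and 3 in the libraries, led with Fcer1g, Spi1 and Rac2 and carried Runx1, Gfi1b, Neurl3 and Cd44, markers of blood-forming endothelium. An unnamed E9.5 cluster of 335 cells had Ifitm1, Phlda2, Dlk1, the early endothelial regulator Etv2 and the posterior gene Hoxc9 among its leading genes and a median of 15339 UMIs. Sinusoid-like cells formed a cluster of 93 cells at E9.5, led by Lyve1, Stab2, Mrc1 and Oit3, and 1 of 86 cells later, with Clec4g and Dnase1l3 among its genes, although liver had been removed from the later embryos.

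At the later stages 4 unnamed clusters belonged mostly to single libraries. Groups with Odc1 among their leading genes held 721 cells, 93.5% from E12.5 replicate 1, with Kcne3, Aplnr and Apln, and 701 cells, 95.7% from E12.5 replicate 2, with Meox2. A cluster of 458 cells, 71.8% from E15.5 replicate 2, led with Scn7a, Foxf1, Hoxa5 and Car14 and had 2 of 6 lung markers. Another of 55 cells, 94.5% from the same library, led with Rsad2 and Flrt3. Mixed clusters of 95 and 73 cells joined lymphatic with macrophage genes and endothelial with erythroid genes, at medians of 22316 and 21695 UMIs.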
